A study of Rattus norvegicus with 16 samples.

How the data were processed

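Total RNA from rat adrenal tissue was measured on 16 Affymetrix expression arrays. Per the labels, the mutant rats carried a p27Kip1 mutation and all rats were of a mixed Sprague-Dawley white eye and Wistar-Kyoto strain. RNA was extracted with Trizol and a column kit, amplified, labelled with biotin and hybridized. Of the 16 arrays, 8 held adrenal hyperplasia, 4 held pheochromocytoma, and 4 held adrenomedullary tissue of wild-type rats, 2 of them young and 2 older. Each wild-type array held RNA pooled from 2 or 3 animals, so pools show less than the spread between single animals.

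The deposited values are on the log2 scale, 1 per probe set and array. The submitters' processing notes name RMA as the method (its version is not given), which corrects background, normalizes quantiles over arrays and summarises the probes of a probe set. Which arrays were normalized together is not given. The values lay between 2.41 and 14.54 (log2), and the array medians lay between 6.51 and 6.61. Those limits cover the 31042 of 31099 probe sets that are not controls. The number of arrays limits the precision of every difference.

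The 57 control probe sets were left out of the tests, which left 31042. Symbols came from the platform annotation and were looked up again by Entrez identifier in a rat gene table, where 20758 matched and 0 changed. Exactly 1 symbol belonged to 20826 probe sets, several symbols to 436 and none to 9780. A gene was represented by its probe set with the highest mean log2 value over the 16 arrays, which gave 14217 genes.

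The following choices were made before the data were examined, except where stated. Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes) on the log2 values of all 16 arrays, with 4 group levels and labelled sex as an additive covariate. The fit had 11 residual degrees of freedom and a median prior of 3.97. Benjamini-Hochberg adjustment ran over the 31042 probe sets of a comparison, and an adjusted p under 0.05 passed the test. All tests were two-sided. Each wild-type arm has 2 pools, so the fit lets the 4 groups share 1 estimate of the spread per gene. The comparisons were hyperplasia against young wild type, pheochromocytoma against old wild type, the difference between those effects, pheochromocytoma against hyperplasia, old against young wild type, and labelled female against labelled male hyperplasia on its 8 arrays alone.

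The 23 gene lists were written from general knowledge. They cover the mitotic cell cycle, DNA replication, G1 regulators, sympathoadrenal and neuronal transcription factors, the neuronal cytoskeleton and axon growth, catecholamine synthesis, storage and transport, secretory granule proteins, neuropeptides, targets of hypoxia-inducible factors, human pheochromocytoma susceptibility genes, receptor tyrosine kinases and MAPK feedback, the BMP, Notch and Wnt pathways, ion channels and nicotinic receptors, oxidative phosphorylation, steroid and cholesterol synthesis, genes recalled from the published account of this rat model, and markers of adrenal cortex, macrophages and leukocytes, endothelium, fibroblasts and pericytes, Schwann and sustentacular cells, red blood cells and adipocytes. The published-account list was recalled from memory and could not be checked; such genes would have been chosen on these samples, so it is not independent evidence. The lists were tested in the first 3 comparisons with camera in limma (preset correlation 0.01, Benjamini-Hochberg over the 23 lists), which compares a list with all other genes. Camera with an estimated correlation and fry were the alternatives. Fry asks whether the genes of a list move on balance one way (directional) or change either way (mixed), without comparing them with other genes. List means per array were compared between groups with exact permutation tests. With 8 arrays against 2 an exact permutation test cannot go below p = 0.0222, and with 4 against 2 not below p = 0.0667.

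Genes named in the text were chosen by rule. For each of the first 2 comparisons the rule takes the 10 largest increases and the 10 largest decreases past the threshold with every mutant array on the same side of every wild-type pool. For the other comparisons it takes 5 per direction, without that last condition for the difference of effects. From each list it takes up to 4 passing members with the largest changes, or, where fewer pass, the members with the smallest p up to 2. It adds Cdkn1b and every gene of the published-account list.

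The alternatives were no sex covariate, only the arrays of the groups compared, an intensity trend with a robust prior, leaving out the 30% dimmest probe sets, quantile normalization over the 16 arrays, centring each array on its median, array weights, the replicate number as a block, the mean of the adrenal cortex markers as a covariate, the mean of all probe sets of a gene, and leaving out each array in turn. Chosen after the data were seen were the Xist level in place of the labelled sex, leaving out the hyperplasia arrays whose Xist level disagreed with the labelled sex, the split of the hyperplasia arrays by Xist, leaving out each array, rescaling and the sex alternatives for the lists, the tests of the control probe sets, and, for the number of genes shared by hyperplasia and pheochromocytoma, all alternatives but no sex covariate, the cortex covariate, quantile normalization and leaving out the dimmest probe sets. Whether values on an array stood apart from its group was tested with Dixon's ratio.

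The pipeline was tested on simulated data in which 67 probe sets were changed by 0.5, 67 by 1 and 66 by 2 (log2), and the rest of the 31042 were left unchanged. In the design of the hyperplasia comparison it recovered 26.9%, 80.6% and 98.5% of them and called 4 unchanged probe sets. In the design of the pheochromocytoma comparison it recovered 22.4%, 59.7% and 93.9%, and called 8 unchanged probe sets. The simulations called 141 and 125 probe sets, against 2227 and 4027 in the data. With fewer calls the adjusted threshold was stricter, so these recoveries do not give the sensitivity in the data. Camera found a list of 20 genes raised by 0.5 in both designs, and of 100 unchanged lists 5 and 6 had an unadjusted p under 0.05. The simulated genes were drawn independently of each other. The correlations estimated in the real lists reached 0.502 for the mitotic and 0.689 for the adrenal cortex list, so these rates do not check camera on correlated lists. No pair of arrays was identical, and no array was left out. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.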

Results

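The series compares adrenal tissue of rats with a p27Kip1 (Cdkn1b) mutation with adrenomedullary tissue of wild-type rats, on 16 arrays. At 2 months of age there were 8 arrays of adrenal hyperplasia, 4 labelled female and 4 labelled male, and 2 wild-type pools, of 2 and 3 animals. The older rats gave 4 pheochromocytomas, tumours of the catecholamine-producing chromaffin cells, 3 from rats of 8 months labelled female and 1 from a rat of 9 months labelled male. Their wild-type arrays were a pool of 2 animals of 10 months and a pool of 2 animals of 12 and 17 months. Arrays of the same group correlated at 0.981 to 0.996 across probe sets and arrays of different groups at 0.94 to 0.987. Values below are log2 values, differences are log2 differences ± standard error from the limma fit over all 16 arrays, and levels are means ± SD.

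Cdkn1b, the mutated gene, codes for an inhibitor of cyclin-dependent kinases and is represented by 2 probe sets. The brighter one was 11.70 ± 0.10 in hyperplasia (n = 8) and 10.96 ± 0.11 in young wild type (n = 2), a difference of 0.73 ± 0.11 (adjusted p = 0.0017). In pheochromocytoma (n = 4) it was 11.53 ± 0.14 against 10.59 ± 0.20 in old wild type (n = 2), a difference of 0.95 ± 0.13 (adjusted p = 0.000526). The dimmer one went the other way in hyperplasia, by -0.81 ± 0.22 (adjusted p = 0.0394), and differed by 0.10 ± 0.24 in pheochromocytoma (adjusted p = 0.836). In the tumours it was at 3.83 to 4.40 and in old wild type at 4.07 to 4.21. Both lie below the first quartile of all probe sets on those arrays, 4.86 to 4.93. Signal over background was not shown there, so a difference could be missed. Where either probe set lies relative to the mutation is not given in the sources used here, so neither value checks the genotype.

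The first comparison asks which genes differed between hyperplasia and age-matched wild-type medulla. Gal, which codes for the neuropeptide galanin, was 11.69 ± 0.70 in hyperplasia (n = 8) and 7.44 ± 0.46 in young wild type (n = 2), a 19-fold difference. Cdkn2a, whose products p16 and p19Arf restrain the cell cycle, was 8.68 ± 0.43 against 4.50 ± 0.77. Dgkh, a diacylglycerol kinase, was 11.61 ± 0.32 against 8.04 ± 0.15, an 11.8-fold difference. Lrat, which esterifies retinol, had the largest decrease by the naming rule, from 9.97 ± 0.60 to 7.34 ± 0.89. The neuropeptide gene Npy fell from 13.22 ± 0.12 to 11.90 ± 0.38 and Vip, another neuropeptide gene, from 8.80 ± 0.01 to 6.90 ± 0.58. In this comparison 2227 of 31042 probe sets passed the test, 1292 higher and 935 lower in hyperplasia, and 474 of them differed by at least 2-fold. Counted once per gene, 1208 of 14217 genes passed, 734 higher and 474 lower.

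The other large increases were Smoc2 at 4.65 ± 0.63 (adjusted p = 0.000749), Sctr, the secretin receptor, at 3.85 ± 0.35 (adjusted p = 3.22e-05), and Epcam, an epithelial adhesion molecule, at 3.82 ± 0.69 (adjusted p = 0.00421). Krt19, a keratin of simple epithelia, rose by 3.11 ± 0.20 (adjusted p = 2.93e-06). Rbp4, Tspan8 and Tac3, the gene of neurokinin B, rose by 3.12, 2.88 and 2.87. Besides Lrat and Vip, the largest decreases were those of Eaf2 (-2.53), Spp1 (-2.27), Nptx1 (-2.20), Ralyl (-2.09), Prmt8 (-1.91), Hspa1a (-1.89), Slc1a1 (-1.87) and Nxpe2 (-1.86). Spp1 codes for osteopontin, Hspa1a for a heat shock protein and Slc1a1 for a glutamate transporter. For each of these genes all 8 hyperplasia arrays lay on the same side of both wild-type pools. The young wild-type means of Smoc2 (4.45), Cdkn2a (4.50), Sctr (4.75), Rbp4 (4.70) and Tac3 (4.21) lay below the first quartile of all probe sets on those arrays, 4.81, where signal over background was not shown. Of these 20 genes Smoc2, Gal, Cdkn2a, Sctr, Dgkh and Krt19 passed whichever array was left out, and 9 passed with the cortex marker mean as a covariate, where 6 of the 20 differences were smaller by over 1.5 times. Hspa1a was at -1.06 without young wild-type pool 1.

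**Figure D1:**
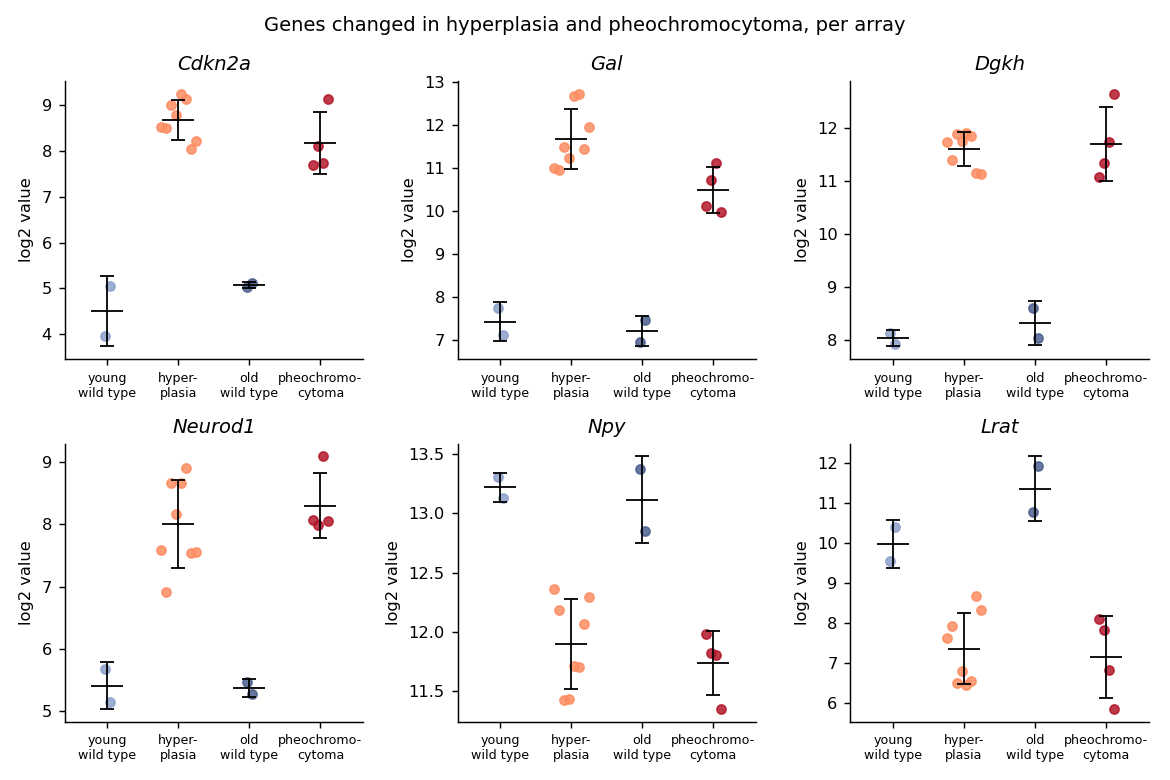
Log2 values of 6 genes on each array, 1 dot per array, in young wild type (n = 2), hyperplasia (n = 8), old wild type (n = 2) and pheochromocytoma (n = 4), with bars at the mean ± SD. Cdkn2a, Gal, Dgkh and Neurod1 were higher, and Npy and Lrat lower, on every mutant array than on the wild-type pools of the same set.

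Genes of cell division were higher in hyperplasia. Of 24 measured mitotic genes 7 rose, 0 fell and 17 did not pass (17 higher and 0 lower adjusted over the list alone), and the list passed camera (adjusted p = 4.33e-09), but not with an estimated correlation (adjusted p = 0.272 with an estimated correlation). Kif2c rose by 1.89 ± 0.37, Prc1 by 1.33 ± 0.33, Top2a by 1.32 ± 0.36 and Aurkb by 1.26 ± 0.28. Of 18 DNA replication genes 9 rose, 0 fell and 9 did not pass (13 higher and 0 lower adjusted over the list alone), with a camera adjusted p of 1.35e-08 and adjusted p = 0.105 with an estimated correlation. Cdt1, a licensing factor of replication, rose by 1.38 ± 0.22, Uhrf1 by 1.09 ± 0.22, Mcm4 by 0.84 ± 0.21 and Fen1 by 0.82 ± 0.15. Of 21 G1 regulators 7 rose, 1 fell and 13 did not pass (8 higher and 4 lower adjusted over the list alone), with a camera adjusted p of 0.00578 and adjusted p = 0.065 with an estimated correlation. The risers include inhibitors as well as drivers of the cycle: Cdkn2a, Cdkn2c, which codes for the inhibitor p18 (1.74 ± 0.12, adjusted p = 7.68e-06), and the growth-promoting factor Myc (1.05 ± 0.22). The gene that fell was Ccnd2, cyclin D2, at -1.60 ± 0.26. Across the same arrays the mean of the adrenal cortex markers was lower by 0.865 in hyperplasia. The red blood cell mean was also lower on all 8 hyperplasia arrays (6.336 to 7.136) than in the pools (7.155 and 7.324, exact permutation p = 0.0667, 0.118 adjusted over 23 lists). The means of the other cell type lists overlapped the pools. The mean of the mitotic list was 6.63 to 6.79 on the 4 hyperplasia arrays without Xist, the RNA of the inactive X chromosome, 6.15 to 6.30 on the 4 with it and 5.60 to 5.70 in the pools (exact permutation p = 0.0286 between the 2 sets of 4, the smallest that 70 splits allow, 0.11 adjusted over 23 lists). Of the 12 genes named from these lists, Cdkn2a, Cdkn2c and Cdt1 passed whichever array was left out, 5 passed without young wild-type pool 1, 5 without pool 2 and 4 with the cortex covariate. With that covariate the differences of Kif2c (0.88), Aurkb (0.71) and Ccnd2 (-0.98) were smaller by over 1.5 times, those of 5 others were smaller by less, and 4 were as large or larger, among them Prc1 at 1.68 and Top2a at 1.56. Their standard errors were a median of 1.27 times as large, and the 3 lists passed camera with the covariate. The young wild-type mean of Uhrf1 (4.18) lay below the first quartile of those arrays, 4.81, so that signal over background was not shown there. Uhrf1 was at 0.72 without pool 1 and Myc at 0.64 without pool 2.

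Neuronal and sympathoadrenal genes were also higher in hyperplasia. Of 16 measured transcription factors of the sympathoadrenal and neuronal lineage 6 rose, 0 fell and 10 did not pass (8 higher and 0 lower adjusted over the list alone), with a camera adjusted p of 1.55e-05 and adjusted p = 0.0887 with an estimated correlation. Neurod1, a neuronal and endocrine differentiation factor, rose by 2.59 ± 0.43 (adjusted p = 0.00277), Gata2 by 1.34 ± 0.23, Sox4 by 1.15 ± 0.19 and Eya1 by 1.12 ± 0.15. Of 18 genes of the neuronal cytoskeleton and axon growth 8 rose, 0 fell and 10 did not pass (10 higher and 2 lower adjusted over the list alone), with a camera adjusted p of 4.31e-05 and adjusted p = 0.105 with an estimated correlation. Rbfox3, the neuronal nuclear antigen NeuN, rose by 1.89 ± 0.28, Prph, the intermediate filament peripherin, by 1.04 ± 0.15, Stmn4 by 1.00 ± 0.14 and Elavl4 by 0.87 ± 0.20. The cortex marker mean moved with these lists too, by -0.865. Rbfox3, Eya1, Prph and Stmn4 passed whichever array was left out, and 4 of the 8 genes passed without young wild-type pool 2 and 4 with the cortex covariate, where 2 of the 8 differences, those of Eya1 and Elavl4, were smaller by over 1.5 times. The mean of the transcription factors was 9.25 to 9.47 on the hyperplasia arrays with Xist and 8.83 to 9.22 on those without it, against 8.39 to 8.66 in the pools. Nr4a1, an immediate early transcription factor in this list, was higher with Xist by 3.04 ± 0.19. It carries part of the difference by Xist, which therefore does not describe the list as a whole.

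Genes of chromaffin cell function did not move in 1 direction. Of 13 catecholamine genes 1 rose, 2 fell and 10 did not pass (2 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.8). The noradrenaline transporter Slc6a2 rose by 1.33 ± 0.22 (adjusted p = 0.00262), while Pnmt, which makes adrenaline, fell by 0.64 on the log2 scale (adjusted p = 0.0435) and the sulfotransferase Sult1a1 by 1.63 (adjusted p = 0.00779). Of 18 neuropeptides Gal rose, 3 fell, namely Vip, Npy and Calca (-1.08 ± 0.16), and 14 did not pass (2 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.177). Of 14 secretory granule genes 0 passed in limma, overall or adjusted over the list alone (camera adjusted p = 0.803). Of the 7 members of these lists named as past the threshold, Gal and Calca passed whichever array was left out, 4 passed without young wild-type pool 1, and 2 without pool 2 and 2 with the cortex covariate, where of the 7 differences only that of Pnmt was smaller by over 1.5 times. Among the granule genes the members with the smallest p were Cpe at -0.38 (adjusted p = 0.0911) and Snap25 at 0.37 (adjusted p = 0.268). Over all probe sets 7006 had an unadjusted p under 0.05.

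Adrenal cortex markers were lower in hyperplasia. Of 12 measured markers 0 rose, 2 fell and 10 did not pass (0 higher and 8 lower adjusted over the list alone), with a camera adjusted p of 4.03e-05 and adjusted p = 0.453 with an estimated correlation. Those that fell were the lipoprotein receptor Scarb1 at -1.22 ± 0.34 and the steroidogenic electron carrier Fdx1 at -0.80 ± 0.21. Both are members of the cortex marker mean, so a fit with that mean as a covariate is no separate test of them. The mean of the list was 10.26 ± 0.29 on the 8 hyperplasia arrays and 11.13 ± 0.11 in the 2 pools, with an exact permutation p of 0.0222, the smallest that 45 splits allow (0.0567 adjusted over 23 lists). Of 13 steroid and cholesterol synthesis genes 0 rose, Dhcr7 fell (-1.35 ± 0.33) and 12 did not pass (0 higher and 1 lower adjusted over the list alone), with a camera adjusted p of 0.00739 and adjusted p = 0.479 with an estimated correlation. Cyp51 was at -0.72 ± 0.26 (adjusted p = 0.114). Of 22 oxidative phosphorylation genes 0 rose, Ndufa5 fell (-0.62 ± 0.16, adjusted p = 0.029) and 21 did not pass (0 higher and 1 lower adjusted over the list alone), with a camera adjusted p of 0.00739 and adjusted p = 0.479 with an estimated correlation. Sdha was at -0.43 ± 0.14 (adjusted p = 0.0805). Both lists missed the threshold without young wild-type pool 2, at adjusted p = 0.743 for steroid and cholesterol synthesis (1.82e-07 to 0.743 over its alternatives) and 0.375 for oxidative phosphorylation (0.000635 to 0.479), and with the cortex covariate, at 0.104 and 0.149. Scarb1, Fdx1, Dhcr7 and Ndufa5 each missed it when either young pool was left out and with the cortex covariate, where all 4 differences were smaller by over 1.5 times.

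The list of hypoxia-inducible factor targets also holds Epas1 and Hif1a, genes of the factors themselves. Of its 26 genes 3 rose, 0 fell and 23 did not pass (3 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.627). The risers were Epas1, the gene of the hypoxia-inducible factor HIF-2α, at 1.03 ± 0.15, Mxi1 at 0.49 ± 0.13 and Hk1, a hexokinase, at 0.46 ± 0.10. The median of this list was -0.017 and its mean 0.03. Epas1 passed whichever array was left out, Mxi1 and Hk1 missed the threshold when either young wild-type pool was left out, and 0 of the 3 passed with the cortex covariate, where 0 of the 3 differences were smaller by over 1.5 times. Mxi1 was at 0.31 without pool 2. Of 15 human susceptibility genes for pheochromocytoma Epas1 rose, 0 fell and 14 did not pass (1 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.456), and Sdhaf2 was at -0.34 ± 0.10 (adjusted p = 0.0535). Of the 7 genes recalled from the published account of this model 6 rose and 1 fell (the same adjusted over the list alone, camera adjusted p = 1.35e-08 and adjusted p = 0.0108 with an estimated correlation). That list was written from memory and could not be checked against the account, and because such genes would have been chosen on these samples it is not independent evidence. They are Gal, Cdkn2a, Dgkh, Neurod1, Cdkn2c and Bmp7 (1.16 ± 0.17, adjusted p = 0.00137), which rose, and Bex1 (-0.49 ± 0.10, adjusted p = 0.00704), which fell.

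The number of probe sets past the threshold in hyperplasia was 855 without young wild-type pool 1 and 375 without pool 2, where the lone pool is assumed to vary like the other groups. It was 223 with the cortex marker mean as a covariate and 689 without the 4 hyperplasia arrays whose Xist level disagreed with the labelled sex and without a sex covariate. The 3′ minus 5′ signal of the hexokinase control probe sets, a measure of RNA and labelling quality, was 1.21 to 1.64 in hyperplasia and 1.06 to 1.18 in young wild type. Of 66 named genes past the threshold 31 stayed past it without pool 1, 20 without pool 2 and 21 with the cortex covariate.

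The second comparison asks which genes differed between pheochromocytoma and older wild-type medulla. The tumours came from rats of 8 and 9 months and the pools from older animals, so age goes with genotype here. Old pool 1, of 10 months, was labelled female and old pool 2, of 12 and 17 months, male, so the pools differ in age and sex. Tac3, the gene of neurokinin B, was 8.98 ± 2.07 in the tumours (n = 4) and 4.58 ± 0.06 in old wild type (n = 2), with a difference of 4.68 ± 0.86 in the fit with labelled sex. Smoc2 was 8.56 ± 0.64 against 4.48 ± 0.82, Gal 10.49 ± 0.53 against 7.22 ± 0.36, Dgkh 11.70 ± 0.69 against 8.33 ± 0.41 and Cdkn2a 8.16 ± 0.67 against 5.07 ± 0.07. Lrat was 7.14 ± 1.03 against 11.35 ± 0.81, the largest decrease by the naming rule. Npy was 11.74 ± 0.27 against 13.12 ± 0.37. In this comparison 4027 of 31042 probe sets passed the test, 2332 higher and 1695 lower in the tumours, and 1077 differed by at least 2-fold. The balance of directions depended on the scaling, with 2047 higher and 2108 lower after quantile normalization and 1770 higher and 2335 lower after median centring. Counted once per gene, 2180 of 14217 genes passed, 1258 higher and 922 lower.

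The other large increases in the tumours were Epcam at 3.15 ± 0.76 (adjusted p = 0.0151), the potassium channel gene Kcnq5 at 3.12 (adjusted p = 0.000214), the collagen gene Col24a1 at 3.07 (adjusted p = 0.000604), the T-box factor Tbx4 at 3.06 (adjusted p = 0.000147) and Krt19 at 3.00 (adjusted p = 1.22e-05). Besides Lrat, the largest decreases were those of Ass1 (-3.47), an enzyme of arginine synthesis, Cox8b (-3.45), Fam110c (-3.36), Vil1 (-3.14), Hcrtr2, an orexin receptor (-3.11), Scgb1c1 (-2.92), Nfil3 (-2.87), Creb3l1 (-2.82) and Prlr, the prolactin receptor (-2.80). Their adjusted p ran from 0.000315 for Vil1 to 0.0427 for Ass1. For each of these genes all 4 tumours lay on the same side of both old wild-type pools. The old wild-type means of Tac3 (4.58), Smoc2 (4.48), Krt19 (4.72) and Kcnq5 (4.90) lay below the first quartile of those arrays, 4.92 and 4.93. Of these 20 genes 12 passed whichever array was left out and 3 with the cortex marker mean as a covariate, where 10 of the 20 differences were smaller by over 1.5 times. Without old wild-type pool 2 Ass1 was at -1.63 and Hcrtr2 at -1.78, Nfil3 too was smaller by over 1.5 times, and none of the 3 passed the threshold, and Ass1 was at -5.57 without old pool 1. The tumours were labelled 3 female and 1 male against 1 pool of each. Of the 20 genes with the largest changes 13 also differed between the hyperplasia arrays with and without Xist, all 13 in the direction of the tumours, among them Ass1 (-2.46), Scgb1c1 (-2.13), Hcrtr2 (-2.08), Epcam (1.97), Smoc2 (1.74), Fam110c (-1.66) and Lrat (-1.56). Of the 20 genes of the hyperplasia comparison 8 did so, again all in the direction of the mutant group. That comparison was balanced by Xist, which 4 of its 8 hyperplasia arrays and 1 of its 2 young pools carried. With the Xist level in place of the labelled sex 0 of its 66 named differences moved by over 1.5 times. Both argue against an additive effect of the sex shown by Xist as the source of these differences. All 20 of either comparison passed with the Xist level in place of the labelled sex, where Lrat was at -4.02, Epcam at 2.97 and Smoc2 at 3.91 in the tumours.

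Cell cycle genes were higher in the tumours as well. Of 24 mitotic genes 8 rose, 0 fell and 16 did not pass (15 higher and 0 lower adjusted over the list alone), with a camera adjusted p of 3.19e-06 and adjusted p = 0.405 with an estimated correlation. Kif2c rose by 2.05 ± 0.41, Bub1, a spindle checkpoint kinase, by 1.77, Aurkb by 1.63 and the proliferation marker Mki67 by 1.53 (adjusted p = 0.0464). Of 18 DNA replication genes 7 rose, 0 fell and 11 did not pass (8 higher and 0 lower adjusted over the list alone), with a camera adjusted p of 5.49e-05 and adjusted p = 0.339 with an estimated correlation. Mcm4 rose by 1.15, Cdt1 by 1.04, Mcm6 by 0.99 and Mcm2 by 0.79. Of 21 G1 regulators 6 rose, 1 fell and 14 did not pass (10 higher and 2 lower adjusted over the list alone), with a camera adjusted p of 0.00732 and adjusted p = 0.0863 with an estimated correlation. Cdkn2a (3.12 ± 0.42), the pocket protein gene Rbl1 (1.20), Cdkn2c (1.00, adjusted p = 0.000735) and Cdkn1b rose. Without old wild-type pool 1 the G1 list had an adjusted p of 0.0627 (5.13e-08 to 0.0863 over its alternatives). The fibroblast and pericyte mean was higher on all 4 tumours (8.05 to 8.55) than in the pools (7.87 and 7.90). The adipocyte mean was lower (5.701 to 5.879 against 5.883 and 6.442), and the macrophage, endothelium, Schwann and red blood cell means overlapped the pools. The cortex marker mean was lower by 1.25 on the same arrays. Of the 12 genes named from these lists 7 passed whichever array was left out, 9 without old wild-type pool 1, 8 without pool 2, 11 without pheochromocytoma 4 and 0 with the cortex covariate. With that covariate the differences of Cdkn2a (1.96), Kif2c (0.57) and Aurkb (0.83) were smaller by over 1.5 times, those of 5 others were smaller by less, and those of Mki67 (2.05), Cdt1 (1.29), Mcm6 (1.17) and Mcm2 (1.10) were larger. Their standard errors were a median of 1.46 times as large, and the 3 lists passed camera with the covariate. The old wild-type mean of Bub1 (4.14) lay below the first quartile of those arrays, 4.92 and 4.93.

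Neuronal genes were higher in the tumours. Of 18 genes of the neuronal cytoskeleton and axon growth 11 rose, 0 fell and 7 did not pass (12 higher and 2 lower adjusted over the list alone), with a camera adjusted p of 0.000152 and adjusted p = 0.236 with an estimated correlation. Stmn4 rose by 1.28, Rbfox3 by 1.21, Dpysl3 by 1.21 and Stmn1 by 1.19. Of 16 sympathoadrenal and neuronal transcription factors 7 rose, 0 fell and 9 did not pass (9 higher and 0 lower adjusted over the list alone), with a camera adjusted p of 0.004 and adjusted p = 0.339 with an estimated correlation. Neurod1 rose by 2.97 ± 0.48 (adjusted p = 0.00181), Eya1 by 1.41, Isl1 by 0.83 and Sox4 by 0.81. Here too the cortex marker mean moved with the lists, by -1.25. Neurod1, Eya1, Stmn4 and Stmn1 passed whichever array was left out, and 0 of the 8 passed with the cortex covariate, where the differences of Eya1, Stmn1, Isl1 and Sox4 were smaller by over 1.5 times. Without old wild-type pool 2 Rbfox3 was at 0.67, and without old pool 1 it was at 1.83 and Sox4 at 0.51.

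Of 14 secretory granule genes 4 rose in the tumours, 0 fell and 10 did not pass (4 higher and 0 lower adjusted over the list alone), with a camera adjusted p of 0.0158 and adjusted p = 0.458 with an estimated correlation. They were Vgf, a neuropeptide precursor (2.02 ± 0.53), Cplx2 (1.47), Snap25 (0.79), both parts of the machinery of exocytosis, and Scg3, a granin (0.64). The list had an adjusted p of 0.794 without old wild-type pool 2 and 0.832 with the cortex marker mean as a covariate (0.000115 to 0.832 over its alternatives). Of 13 catecholamine genes 2 rose, 1 fell and 10 did not pass (4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.661). Ddc, which makes dopamine, rose by 0.85 (adjusted p = 0.0104), the vesicular monoamine transporter Slc18a1 rose by 0.70 (adjusted p = 0.0315) and Sult1a1 fell by 1.48. Of 18 neuropeptides Gal rose, 3 fell, namely Vip (-1.80), Npy (-1.40 ± 0.27, adjusted p = 0.00495) and Pdyn (-1.02), and 14 did not pass (1 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.291). The cortex marker mean was lower by 1.25. Of the 11 genes named here as past the threshold Gal passed whichever array was left out, 7 passed without old wild-type pool 1, 7 without pheochromocytoma 4, 2 without old pool 2 and 0 with the cortex covariate, where 8 of the 11 differences were smaller by over 1.5 times. Without old pool 2 Ddc was at 0.42, Slc18a1 at 0.29, Scg3 at 0.31 and Sult1a1 at -0.73, and without old pool 1 they were at 1.34, 1.16, 1.01 and -2.33. Vgf was at 1.17 without pheochromocytoma 4.

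Adrenal cortex markers were lower in the tumours. Of 12 markers 0 rose, 7 fell and 5 did not pass (0 higher and 12 lower adjusted over the list alone), with a camera adjusted p of 2.63e-06 and adjusted p = 0.343 with an estimated correlation. The angiotensin receptor Agtr1b fell by 2.10, the corticotropin receptor partner Mrap by 1.96, the steroidogenic transcription factor Nr5a1 by 1.85 and Soat1 by 1.41. The list mean was 10.41 ± 0.56 in the 4 tumours and 11.66 ± 0.30 in the 2 pools (exact permutation p = 0.0667, the smallest that 15 splits allow, 0.153 adjusted over 23 lists). Of 13 steroid and cholesterol synthesis genes 0 rose, 4 fell and 9 did not pass (0 higher and 4 lower adjusted over the list alone), with a camera adjusted p of 0.00117 and adjusted p = 0.437 with an estimated correlation. Idi1 (-1.78), Dhcr7 (-1.58), Insig1 (-1.41) and Cyp51 (-1.22) fell. Without old wild-type pool 2 this list had an adjusted p of 0.13 (2.6e-05 to 0.437 over its alternatives). Of 22 oxidative phosphorylation genes 0 rose, 7 fell and 15 did not pass (0 higher and 9 lower adjusted over the list alone), with a camera adjusted p of 5.49e-05 and adjusted p = 0.365 with an estimated correlation. Ndufa5 of complex I fell by 1.75 (adjusted p = 0.000124), Uqcrc2 and Uqcrfs1 of complex III by 0.64 and 0.58, and Sdha of complex II by 0.60. Of the 12 genes named from these lists Ndufa5 alone passed without old wild-type pool 2 and with the cortex covariate, where 8 of the 12 differences were smaller by over 1.5 times and that of Nr5a1 turned, and 6 passed without pheochromocytoma 4. Agtr1b, Mrap, Nr5a1 and Soat1 are members of the cortex marker mean, so their values with the covariate are no separate test of them. Without old pool 2 Agtr1b was at -1.37, Idi1 at -1.02, Cyp51 at -0.57 and Insig1 at -0.51, and without old pool 1 Cyp51 was at -1.96 and Insig1 at -2.44.

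Of 15 human susceptibility genes for pheochromocytoma 2 rose, 4 fell and 9 did not pass in the tumours (2 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.661). The receptor tyrosine kinase Ret rose by 1.22 ± 0.35 (adjusted p = 0.0319) and Epas1 by 0.60, while the succinate dehydrogenase subunits Sdha and Sdhb fell by 0.60 (adjusted p = 0.0207) and 0.48 (adjusted p = 0.0245). The median of this list was -0.132 with a camera direction down, and its mean was 0.018. Of 26 genes in the list of hypoxia-inducible factor targets, which also holds Epas1, 3 rose, 2 fell and 21 did not pass (4 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.896). Ankrd37 (0.63) and Epas1 rose, and Ddit4 (-0.85) and the glycolytic enzyme Pgk1 (-0.49) fell. The median of the list was -0.046 with a camera direction down, and its mean was 0.015. The cortex marker mean was lower by 1.25. Of the 7 genes named from these lists 0 passed without old wild-type pool 2, without pheochromocytoma 4 or with the cortex covariate, and 6 passed without old pool 1. With the covariate 5 of the 7 differences were smaller by over 1.5 times. Without old pool 2 Ddit4 was at -0.32 and Ankrd37 at 0.33, and without old pool 1 they were at -1.46 and 0.98. With the cortex covariate Epas1 was at 0.20 (adjusted p = 0.782, in a range of 0.0165 to 0.782) and Pgk1 at -0.20 (adjusted p = 0.678, in a range of 0.00611 to 0.678), and Epas1 was at 0.39 without pheochromocytoma 4. Of the 7 genes recalled from the published account, unchecked and not independent evidence, 6 rose and 1 did not pass (6 higher and 0 lower adjusted over the list alone, camera adjusted p = 2.63e-06 and adjusted p = 0.0284 with an estimated correlation). Bmp7 rose by 0.72 (adjusted p = 0.0235), and Bex1 differed by 0.09 ± 0.11 (adjusted p = 0.62).

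The number of probe sets past the threshold in pheochromocytoma was 466 without old wild-type pool 2, with the lone pool assumed to vary like the other groups, and 2159 without pheochromocytoma 4. It was 836 when the fit held only the 6 arrays compared and 25 with the cortex marker mean as a covariate. Of 83 named genes past the threshold 26 stayed past it without pool 2, 52 without pheochromocytoma 4 and 4 with the cortex covariate.

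**Figure D2:**
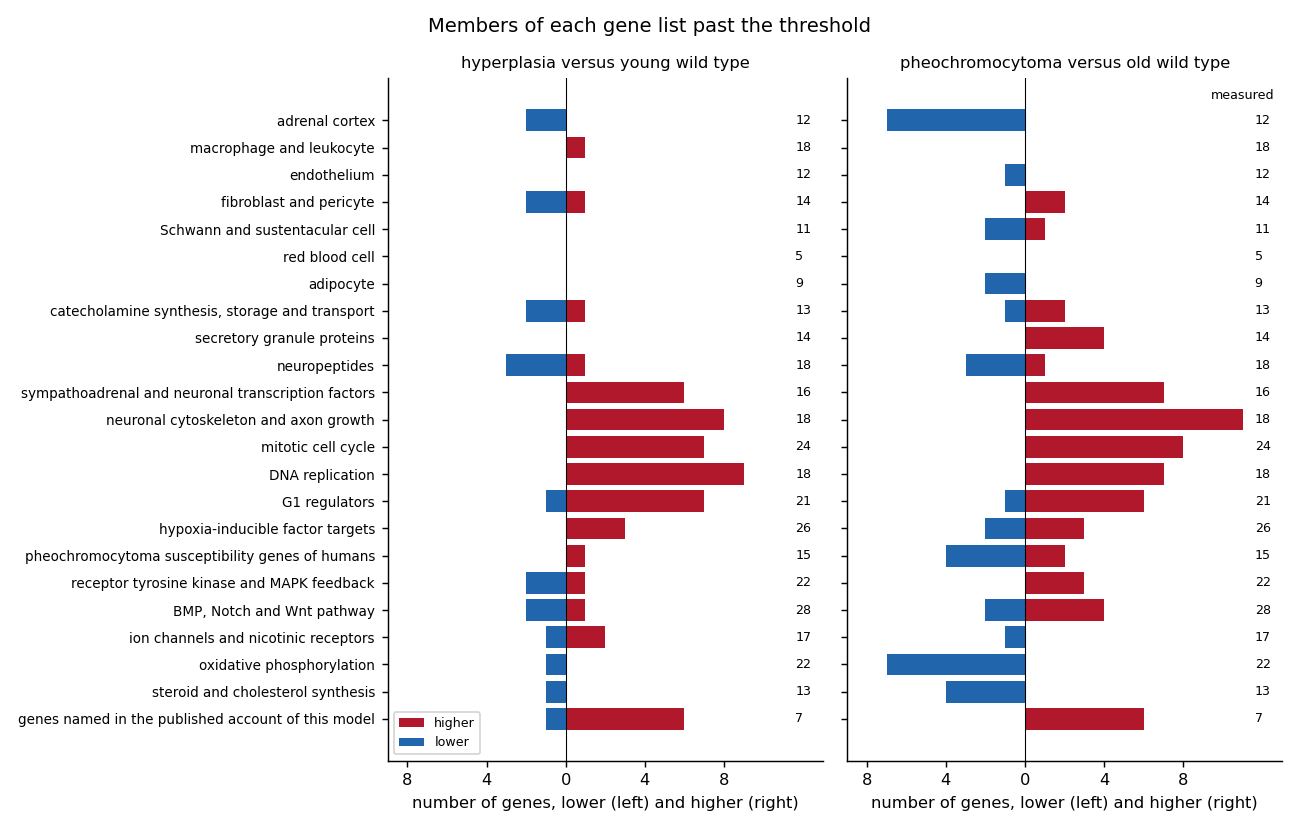
Number of genes per list past the threshold, lower to the left and higher to the right, in hyperplasia against young wild type and in pheochromocytoma against old wild type, with the number measured at the right edge of each panel. In the neuronal cytoskeleton list 8 and 11 of 18 genes were higher, and in the adrenal cortex list 2 and 7 of 12 were lower.

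Many changes of hyperplasia were found in pheochromocytoma too. The comparisons have no array in common, but the fit over 16 arrays gives them a common spread per gene and a common sex term, which the numbers expected of independent lists leave out of account. Of the 734 genes higher in hyperplasia 453 were higher in the tumours (61.7%), where independent lists would share 64.9, and of the 474 lower genes 192 were lower (40.5%), where they would share 30.7. Gal, Cdkn2a, Dgkh, Neurod1, Smoc2, Epcam, Krt19, Tac3 and Kif2c are among the shared increases, and Lrat, Npy, Vip, Dhcr7 and Sult1a1 among the shared decreases. When each comparison was fitted on its own arrays, 151 genes were higher in both, where independent lists would share 13.6, and 55 were lower in both, where they would share 4.99. Over all 16 arrays another 3 genes passed in opposite directions, and 94.1% of the genes called in hyperplasia had the same sign in the tumours. Across all 14217 genes the log2 differences correlated with Pearson r = 0.692 and Spearman rho = 0.602, and genes are not independent replicates. The shared count of 645 was 126 without young wild-type pool 2, 263 without young pool 1, 167 without old pool 2, 206 with only the arrays of each comparison and 6 with the cortex marker mean as a covariate. Those 6 genes were Dgkh (2.63 in hyperplasia and 2.03 in pheochromocytoma with the covariate), Krt19 (3.32 and 3.31), Lix1, Spdl1, Tbx4 and Tcf19.

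**Figure D3:**
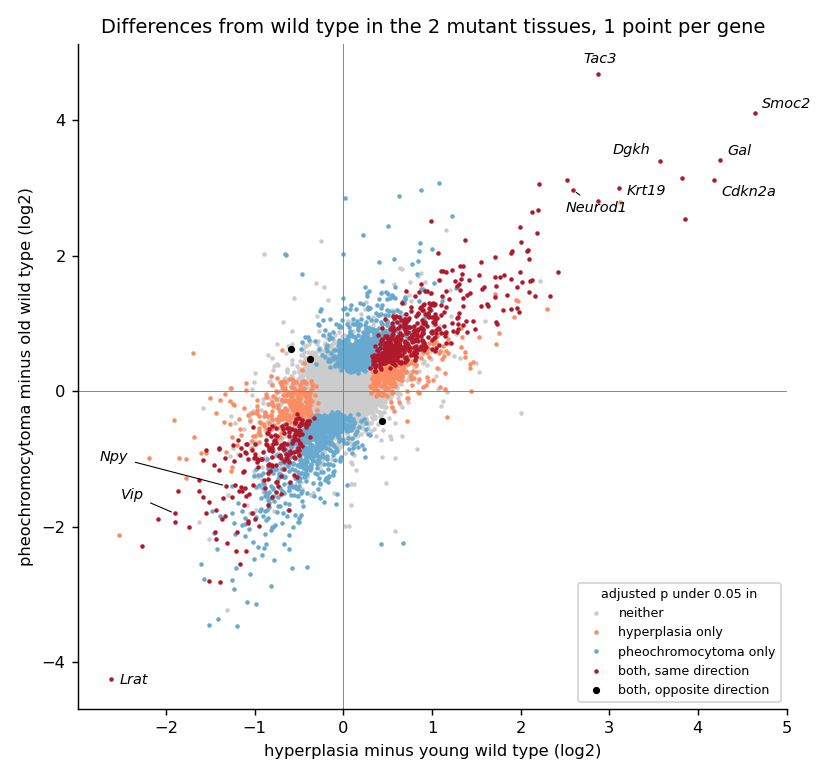
Log2 difference of hyperplasia from young wild type (horizontal axis) against that of pheochromocytoma from old wild type (vertical axis), 1 point per gene, coloured by which comparison it passed. The 453 genes higher in both and the 192 lower in both lie in the upper right and lower left quadrants, and the 3 genes with opposite calls are black.

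**Figure D4:**
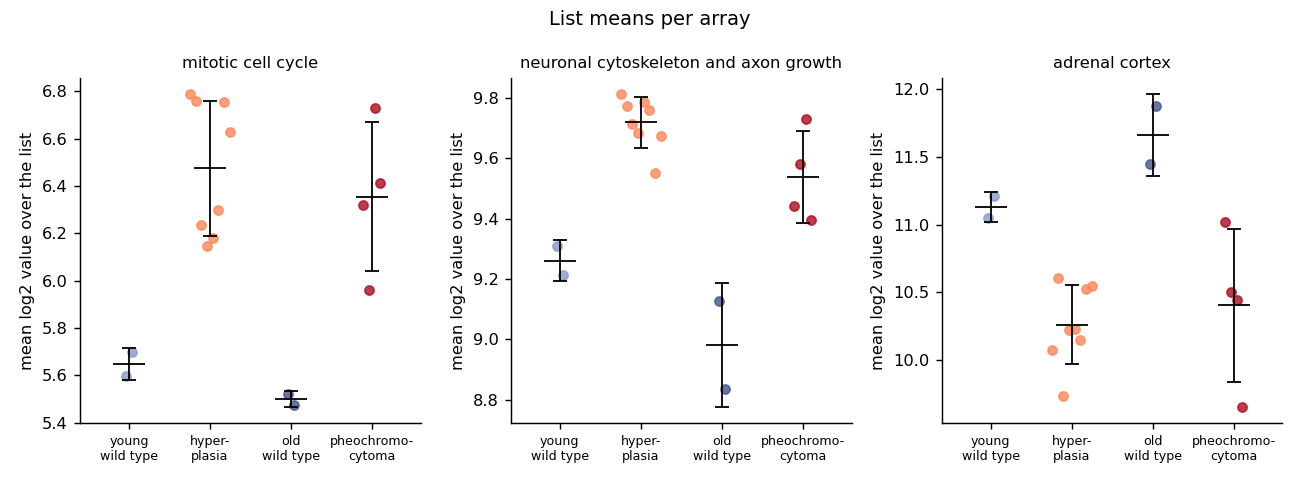
Mean log2 value over the mitotic, neuronal cytoskeleton and adrenal cortex lists on each array, 1 dot per array, with bars at the mean ± SD of young wild type (n = 2), hyperplasia (n = 8), old wild type (n = 2) and pheochromocytoma (n = 4). The cortex mean was lower in hyperplasia by 0.865 and in pheochromocytoma by 1.25 than in the wild-type pools of the same set.

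The difference between the effects in pheochromocytoma and hyperplasia was tested directly. Among the representative probe sets 1 gene passed, the imprinted gene Peg10, with a difference of 1.04 ± 0.16 (adjusted p = 0.0498). Its level was 4.78 in young wild type, 3.54 in hyperplasia, 3.63 in old wild type and 3.45 in pheochromocytoma. Each of these means lay below the first quartile of all probe sets on its arrays, 4.71 to 4.93, where signal over background was not shown. Over all probe sets 6 passed, 4 higher and 2 lower, with 3359 at an unadjusted p under 0.05. The others, named after their values were seen, were other probe sets of Mrps15 (-1.24 ± 0.18), a mitochondrial ribosomal protein, and Fermt2 (1.38 ± 0.19), an integrin-binding protein, and 3 probe sets without a symbol. Cdkn1b did not pass (0.22 ± 0.17, adjusted p = 0.674). Of the lists only the secretory granule proteins passed camera, with a mean difference of 0.42 (adjusted p = 0.0363, adjusted p = 0.854 with an estimated correlation), 0 members past the threshold and 14 that did not pass (1 higher and 0 lower adjusted over the list alone). It missed the threshold in camera with the cortex covariate (adjusted p = 0.0996) and in fry, directional (0.773) and mixed (0.112). The call on this list was lost without pheochromocytoma 3 (adjusted p = 0.056), pheochromocytoma 4 (0.124), old wild-type pool 2 (0.965) or young wild-type pool 1 (0.15), in a range of 3.39e-05 to 0.965 over its alternatives. The number of probe sets was 0 without pheochromocytoma 4 and 489 without old wild-type pool 1, with the lone pool assumed to vary like the other groups.

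Tumours were also compared directly with hyperplasia, and old with young wild type. Higher in pheochromocytoma (n = 4) than in hyperplasia (n = 8) were the matricellular gene Ccn1 (7.99 ± 1.44 against 5.09 ± 0.39), the imprinted RNA Meg3 (12.66 ± 0.23 against 9.87 ± 0.57), Cdh22, Esm1 and Col24a1. Lower were Scgb1c1 (6.47 ± 0.80 against 9.89 ± 1.19), the synaptic vesicle gene Syt1 (5.72 ± 0.23 against 8.97 ± 0.41), Slc6a2 (6.23 ± 0.30 against 9.10 ± 0.31), Ppp2r2c and Ro60. In all, 12019 probe sets passed, 5987 higher and 6032 lower, with 6148 higher and 5797 lower after quantile normalization and 6010 and 5881 after median centring. In old wild type (n = 2) against young (n = 2) 7259 passed, 3186 higher and 4073 lower, a balance that turned to 3573 higher and 3466 lower after quantile normalization and to 3664 and 3475 after median centring. Cwc25 (10.46 ± 2.98 against 7.17 ± 1.38), Fam110c, Iqub, Ezh2 and Fam13c were higher, and Serpinc1, the antithrombin gene (5.13 ± 1.15 against 8.46 ± 0.53), Shoc2, Slc3a1, St18 and Vgf were lower. Cwc25, Fam110c, Fam13c and Vgf missed the threshold without old wild-type pool 2, where Fam13c was at 0.33 (adjusted p = 0.738, in a range of 0.000105 to 0.738), Cwc25 at 1.46, Ezh2 at 1.42 and Iqub at 1.58. The first 3 also missed it without young pool 2, and Fam13c without young pool 1. Fam13c passed in 9 of 27 alternatives and was at 4.40, and Cwc25 at 5.13, without old pool 1. Over 14217 genes the differences between pheochromocytoma and hyperplasia correlated at r = 0.708 with those between old and young wild type. Of the 4809 genes past the threshold in the former 93.2% had the same sign in the latter, 2126 passed there as well in the same direction and 7 in the opposite one. Syt1 was 6.04 in old and 8.59 in young wild type, Slc6a2 5.55 and 7.77, and Meg3 12.43 and 10.51. The 10 arrays from 2-month rats and the 6 from older rats also differed in their poly-A spike controls, RNAs added during preparation, which were 7.31 to 9.18 on the former and 3.57 to 3.72 on the latter. Age and set cannot be told apart in either comparison. Over 4525 genes with 2 probe sets, the differences of both correlated at 0.181 for pheochromocytoma against hyperplasia. They correlated at 0.242 for old against young wild type, and at 0.637 and 0.647 in the first 2 comparisons. Each gene named here stands for a single probe set. The wild-type count was 3969 without old pool 2, 4006 without young pool 2, 4600 without young pool 1 and 2473 with only the 4 wild-type arrays, and the arm left with 1 pool is assumed to vary like the other groups.

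Labelled sex was compared within the 8 hyperplasia arrays, 4 labelled female and 4 labelled male. In limma 0 probe sets passed and 1178 had an unadjusted p under 0.05. Xist, the RNA that silences 1 X chromosome in females, and Eif2s3y, a gene of the Y chromosome, did not follow the labels on 6 of the 10 arrays from 2-month rats. Xist was 9.48 to 10.49 on 5 and 3.40 to 3.92 on the other 5 of these arrays, and Eif2s3y was 9.36 to 10.73 wherever Xist was low and 3.01 to 3.28 wherever it was high. Hyperplasia 1 and 2 and young wild-type pool 2 were labelled female and lacked Xist. Hyperplasia 5 and 6 and young wild-type pool 1 were labelled male and carried Xist. On the 6 arrays from older rats both transcripts followed the labels. The main fit used the labelled sex, so it does not adjust for the sex that these transcripts show on the mismatched arrays.

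**Figure D5:**
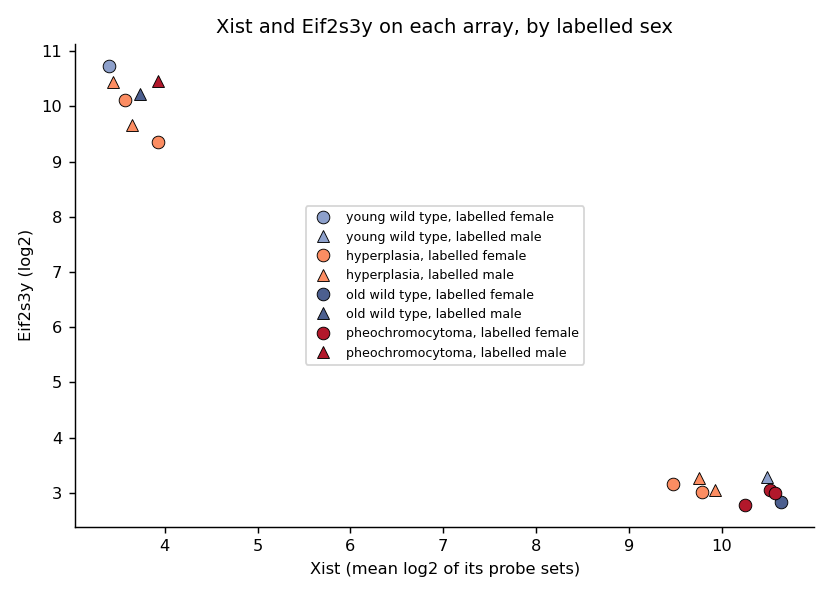
Xist (horizontal axis, mean log2 of 4 probe sets) against Eif2s3y (vertical axis, log2), 1 point per array, with circles for arrays labelled female, triangles for arrays labelled male and colours for the 4 groups. Every array carries 1 of the transcripts, and 3 circles lie among the arrays without Xist and 3 triangles among those with it.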

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

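The tests of mixed RNA, of exchanged sex labels, of separate preparation and of age, and the split by Xist, were chosen only after the result was seen, and the cortex tests gained 1 condition, that the bound hold without each slope array, after their bounds were written and before their values were computed.

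Adrenal cortex markers moved with both main comparisons, by -0.865 in hyperplasia and -1.25 in pheochromocytoma, and the abundant marker Star was at 12.29 and 12.78 in the mutant groups against 13.25 and 13.74 in wild type. The slope of each called gene on the cortex mean, fitted in the other mutant tissue alone, predicted a median share of 0.152 of the decreases in hyperplasia (95% bootstrap interval over genes 0.108 to 0.192) and 0.082 of the increases (0.058 to 0.099), and in pheochromocytoma 0.35 of the decreases (0.317 to 0.387) and 0.249 of the increases (0.209 to 0.289). Both hyperplasia values met the bound of 0.25 set beforehand as excluding less cortex as the cause, but that bound ignored the spread between the 4 slope arrays, without 1 of which the shares reached 0.259 and 0.267, and the tumour values or their intervals lie above it. The tumour shares rest on slopes from the 8 hyperplasia arrays. There the cortex mean was 10.085 with Xist and 10.44 without it, with overlapping arrays (exact permutation p = 0.114). The tumours were labelled 3 female and 1 male against 1 pool of each. Differences by sex can therefore enter the tumour shares and were not separated from cortex. With the cortex mean as a covariate the median difference of the called genes went from 0.649 to 0.545 and from -0.67 to -0.533 in hyperplasia and from 0.642 to 0.474 and from -0.77 to -0.449 in pheochromocytoma, and the median standard error went from 0.14 to 0.176 and 0.15 to 0.188, and from 0.152 to 0.219 and 0.175 to 0.237, which each ended calls, so that 78 of 734, 38 of 474, 6 of 1258 and 2 of 922 genes still passed. Less cortex in the dissected mutant tissue may therefore account for part of these differences, and it cannot be told apart from an effect of the mutation, which stays open, because few arrays carry the slopes and the groups differ in both.

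Labelled sex disagreed with Xist and Eif2s3y on 6 of the 10 arrays from 2-month rats. Mixing of RNA from both sexes is argued against, since on none of the 6 did the fainter transcript exceed the arrays without it by more than 0.279. An exchange of arrays between hyperplasia and wild type is argued against as well: 0 of the 6 lay on the wrong side of the midpoint of 7.23 in the mean of 10 tumour-increased genes, with hyperplasia at 8.33 to 9.38 and young wild type at 5.59 to 5.64. In each group as many arrays labelled female lacked Xist as arrays labelled male carried it, a difference of 0. Sex labels exchanged among arrays of the same group would give this. The count restates the mismatch that prompted the test, so it adds no support, and no biological explanation was tested. The labelled split of the 8 hyperplasia arrays called 0 probe sets, a count that all 35 of 35 splits reach by construction. It therefore says nothing about chance. The split that follows Xist called 2720, the highest, with 0 in the next. Eif2s3y was high wherever Xist was low, so this split follows the sex that the 2 transcripts show and the labels do not give. Whether other differences between these arrays add to the count was not tested.

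The arrays from 2-month and from older rats differed in RNAs that no rat makes. The lowest level of the poly-A spike controls on the 2-month arrays was 7.31, and the gap of 3.59 to the older arrays exceeded the widest range within a set, 1.87. Over 4525 genes with 2 probe sets the differences of both probe sets correlated at 0.242 for old against young wild type and at 0.647 for pheochromocytoma against old wild type, a change of -0.405 (interval -0.446 to -0.365, across genes, which are not independent replicates), so separate RNA preparation could account for part of the set difference. Age cannot be told apart from it, because 0 arrays of older rats reached the spike control level of the 2-month set, and the labels give no preparation batches. The CreX hybridization controls did not overlap either, at 13.38 to 13.84 on the 2-month arrays and 13.03 to 13.15 on the older ones. Separate hybridization therefore cannot be told apart from separate preparation. For pheochromocytoma against hyperplasia only the real split, 1 of 100 drawn from 495, called as many as 12019 probe sets, and the highest other called 2. The real split also follows the sets, and every other split mixes them, which puts the set difference into the spread within its groups. These counts therefore show that the sets differ and cannot exclude chance for a difference between the tissues.

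The effects differed between pheochromocytoma and hyperplasia by the test of the difference for 6 probe sets and, by gene, for Peg10 (1.04 ± 0.16, adjusted p = 0.0498). Peg10 kept its call in 5 of 25 alternatives, with adjusted p from 0.0108 to 0.33, and its levels of 3.45 to 4.78 lie near the lower end of the values. The secretory granule list differed by 0.42 (adjusted p = 0.0363), with adjusted p from 3.39e-05 to 0.965 over 26 alternatives, of which 18 kept the call.

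Of 216 values tested within groups, 7 genes and 1 list had an array apart from the rest of its group, and chance marks about 1 in 20 groups. Nptx1 was 3.88 on hyperplasia 4 and 4.66 to 5.02 on the others. Hyperplasia 7 had the lowest Sctr, 7.56 against 8.57 to 8.91, and the highest Vip, 8.19 against 6.32 to 6.98. Pheochromocytoma 3 had the highest Cacna1d (8.67 against 8.29 to 8.35), Idi1 (9.73 against 8.99 to 9.09) and Neurod1 (9.09 against 8.00 to 8.07). Pheochromocytoma 4 had the lowest Sdhb, 11.03 against 11.33 to 11.37, and the highest mean of the endothelium markers, 9.01 against 8.33 to 8.43.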

How the results depend on the processing

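The alternatives that replace the labelled sex by Xist or leave out the mismatched hyperplasia arrays, those that rescale or leave out arrays for the lists, and those for the shared count other than no sex covariate, the cortex mean, quantile normalization and leaving out the dimmest 30%, were chosen after the data were seen. Numbers below are probe sets past the threshold in limma. In hyperplasia 2227 became 223 with the cortex mean as a covariate, 689 without sex and the mismatched hyperplasia arrays, and 375 (without young wild-type pool 2) to 2693 (without hyperplasia 8) when 1 array was left out, with 855 without young pool 1. In pheochromocytoma 4027 became 836 with only the arrays compared, 25 with the cortex mean, and 466 (without old wild-type pool 2) to 4470 (without hyperplasia 8), with 2159 without pheochromocytoma 4. For the difference of effects 6 became 2 without the dimmest 30%, 0 with median centring, 1 with array weights, 3 with the cortex mean, 10 with Xist, 1 without sex and the mismatched arrays, and 0 (without pheochromocytoma 4) to 489 (without old pool 1). For old against young wild type 7259 became 2473 with only those arrays, and 3969 (without old pool 2) to 7735 (without hyperplasia 8), with 4600 and 4006 without young pools 1 and 2. The shared count of 645 genes became 206 with only the arrays compared, 6 with the cortex mean, 240 without sex and the mismatched arrays, and 126 (without young pool 2) to 756 (without hyperplasia 8), with 167 without old pool 2 and 263 without young pool 1. The replicate block gave 89, 571 and 0 in the first 3 comparisons and 38 shared genes, although deviations of same-numbered arrays correlated at only -0.179 to 0.212, so the numbers pair no arrays. Pheochromocytoma against hyperplasia stayed within 1.5 times of 12019 in every alternative, and labelled sex at 0. A lone pool is assumed to vary like the other groups. In pheochromocytoma the count was 4020 without old pool 1 against 466 without old pool 2. With the cortex mean, of the 734 higher and 474 lower genes of hyperplasia 463 and 251 reached the cutoff of the fit without it when only their differences were replaced, 394 and 219 when only their standard errors were, and 260 and 131 when both were (in pheochromocytoma 662 and 321, 441 and 415, and 216 and 101 of 1258 and 922), and the cutoff itself was stricter, so smaller differences, larger standard errors and the cutoff each ended calls. For the other settings the cause was not tested. In pheochromocytoma 49.3% of calls were higher after quantile normalization and 43.1% after median centring in place of 57.9%, and in old against young wild type 50.8% and 51.3% in place of 43.9%; no rescaling moved the median of all probe sets by over 0.1. With the cortex mean the direction (for lists, that of the set test) turned for Snap25 in hyperplasia (-0.029), for Bex1 (-0.012) and Nr5a1 (0.17, a member of the covariate) in pheochromocytoma, for the fibroblast (-0.072), granule (-0.209) and hypoxia (-0.028) lists in hyperplasia, and for the macrophage (-0.12), endothelium (-0.30, adjusted p = 0.0183 in a range of 0.0183 to 0.962) and catecholamine (-0.052) lists in pheochromocytoma. It also turned in pheochromocytoma for endothelium with quantile normalization (0.039), Schwann (-0.076) and ion channel lists (-0.042) with the mean of all probe sets, the receptor tyrosine kinase list in fry (0.02) and the ion channel list with Xist (0.011), where mean and set test can differ in sign. Leaving out 1 array gave -0.001 (without pheochromocytoma 4) to 0.176 (without old pool 1) for Bex1 in pheochromocytoma and -0.793 (without young pool 1) to -0.02 (without young pool 2, camera direction up) for the steroid list in hyperplasia. Of 20 list calls 2, both of the published-account list, held with an estimated correlation, 16 with fry, 18 with fry mixed and 14 of 18 with the cortex mean. Fry mixed also passed 20 of the 27 list results that camera did not call, so holding there says little about a list. When an array was left out 17 to 20 calls held, and all 20 held with each rescaling and sex alternative. Array signal limits the dimmest genes. Recovery of simulated changes of 0.5 was 26.9% and 22.4%, with far fewer probe sets called, and so a stricter threshold, than in the data.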

Other observations

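The values by Xist level and the tests of the control probe sets were computed only after the data were seen. Of 22 measured receptor tyrosine kinase and MAPK feedback genes 1 rose, 2 fell and 19 did not pass in hyperplasia (1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.392). The neurturin receptor Gfra2 rose by 0.82 ± 0.10 (adjusted p = 0.00049), while Egfr fell by 1.39 (adjusted p = 0.00235) and Spry2, a feedback inhibitor of MAPK signalling, by 0.58 (adjusted p = 0.00284). In pheochromocytoma 3 rose, 0 fell and 19 did not pass (4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.896), namely Ret, Gfra2 (0.63) and Etv5 (0.62). There the median was -0.097 with a camera direction down and the mean 0.02. Of 28 genes of the BMP, Notch and Wnt pathways 1 rose, 2 fell and 25 did not pass in hyperplasia (1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.561): Bmp7 rose, and Wnt4 (-1.27) and Id2 (-0.85), a target of BMP signalling, fell. In pheochromocytoma 4 rose, 2 fell and 22 did not pass (5 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.716), with Axin2, a target of Wnt signalling, at 1.14, the Notch ligand Jag1 at 0.91, Hey1 at 0.77 and Bmp2 at -1.27. Of 17 ion channels and nicotinic receptors 2 rose, 1 fell and 14 did not pass in hyperplasia (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.645), with Chrna7 at 1.17, the calcium channel Cacna1b at 0.67 and Gabra3 at -0.69. In pheochromocytoma 0 rose, Chrna4 fell (-0.41) and 16 did not pass (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.951), with a mean of -0.004, a median of -0.048 and a camera direction up. Cacna1d was at 0.68 (adjusted p = 0.055). The cortex marker mean was lower by 0.865 in hyperplasia and 1.25 in pheochromocytoma. Of the 9 genes of these 3 lists named as past the threshold in hyperplasia, Gfra2 and Bmp7 passed whichever array was left out, 6 passed without young wild-type pool 1, 2 without pool 2 and 3 with the cortex marker mean as a covariate, where the differences of Id2 and Wnt4 were smaller by over 1.5 times. Of the 8 in pheochromocytoma 5 passed without old wild-type pool 1, 1 without pheochromocytoma 4 and 0 without old pool 2 or with the cortex covariate, where those of Axin2, Jag1, Hey1 and Bmp2 were smaller by over 1.5 times. Without old pool 2 Hey1 was at 0.16 and Bmp2 at -0.36, and without old pool 1 they were at 1.48 and -2.31. With the cortex covariate Axin2 was at 0.082 (adjusted p = 0.953, in a range of 0.00241 to 0.953) and Jag1 at 0.03 (adjusted p = 0.983, in a range of 0.0225 to 0.983). Chrna4 passed in 3 of 26 alternatives, with adjusted p from 0.025 to 0.431, and its tumour mean of 4.45 lay below the first quartile of those arrays, 4.86 to 4.88.

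Of 18 macrophage and leukocyte genes Cd74 rose in hyperplasia (0.50 ± 0.12), 0 fell and 17 did not pass (5 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.0766), with Csf1r at 0.39 (adjusted p = 0.0669). In pheochromocytoma 0 passed in limma, overall or adjusted over the list alone (camera adjusted p = 0.896), with C1qc at 0.42 (adjusted p = 0.0831) and Cd163 at 0.52 (adjusted p = 0.143). Of 14 fibroblast and pericyte genes Fbln1 rose in hyperplasia (1.48), Pdgfra (-0.80) and Mfap5 (-0.74) fell and 11 did not pass (1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.8). In pheochromocytoma Rgs5, a pericyte marker (2.08), and Fbln1 (0.91) rose, 0 fell and 12 did not pass (5 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0994). Of 12 endothelial genes 0 passed in hyperplasia, overall or adjusted over the list alone (camera adjusted p = 0.631), with Kdr at 0.44 and Tek at -0.34, and in pheochromocytoma Tek fell (-0.64, adjusted p = 0.0412) and 11 did not pass (0 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.896), with Vwf at 0.67. Of 11 Schwann and sustentacular cell genes 0 passed in hyperplasia, overall or adjusted over the list alone (camera adjusted p = 0.645), with S100b at -0.61 and Mal at -0.58. In pheochromocytoma Mbp rose (0.91), S100b (-1.42) and Cnp (-0.47) fell and 8 did not pass (3 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.951), with a median of -0.016 and a mean of 0.016. Of 9 adipocyte genes 0 passed in hyperplasia (1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.561), with Lpl at 0.46 and Cidec at -0.43, and in pheochromocytoma Adipoq (-1.09) and Cidec (-0.60) fell and 7 did not pass (1 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0826). Of 5 red blood cell genes 0 passed in either comparison (0 higher and 1 lower adjusted over the list alone in hyperplasia, 0 in pheochromocytoma, camera adjusted p = 0.0766 and 0.542), with Alas2 at -0.92, Ahsp at -0.42 and, in pheochromocytoma, Hbb at -0.49. The lower cortex marker means apply here as well. Of the 4 genes of these lists past the threshold in hyperplasia Fbln1 passed without each array and with the cortex covariate, and the other 3 passed neither without young wild-type pool 1, nor without pool 2, nor with the covariate. Of the 8 in pheochromocytoma 7 passed without old wild-type pool 1, 6 without pheochromocytoma 4, Fbln1 alone without old pool 2 and 0 with the covariate, where the differences of Rgs5 and Cnp were smaller by over 1.5 times. The tumour means of Cidec (3.71) and Adipoq (4.27) lay below the first quartile of those arrays, 4.86 to 4.88. Without old pool 2 Adipoq was at -0.46, Cidec at -0.36 and Cnp at -0.23, and without old pool 1 Adipoq was at -1.82 and Cnp at -0.74. All counts of 0 are from limma, where 7006 and 9006 probe sets had an unadjusted p under 0.05 in these comparisons.

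When the 8 hyperplasia arrays were divided by their Xist level, genes chosen after their values were seen included, besides Xist itself (8.22 ± 0.19), Nr4a1, an immediate early transcription factor, at 3.04 ± 0.19 (adjusted p = 1.06e-05) and the mast cell protease gene Mcpt10 at 2.20 ± 0.19 (adjusted p = 0.000142), higher with Xist. Lower with Xist were Serpina3n (-2.57 ± 0.39, adjusted p = 0.00376) and Ass1 (-2.46 ± 0.28, adjusted p = 0.000862). The means of 6 of the 23 lists did not overlap between the 4 arrays with Xist and the 4 without it, at the smallest exact permutation p that 70 splits allow, 0.0286 (0.11 adjusted over the lists): the mitotic, hypoxia and ion channel lists were lower with Xist (by 0.518, 0.067 and 0.11), and the adipocyte list, the transcription factors and the genes of the published account were higher (by 0.193, 0.326 and 0.377). Nr4a1 is a member of the transcription factor list and carries part of its difference. The 3′ minus 5′ signals of control probe sets, a measure of RNA and labelling quality, were lower on all 10 arrays from 2-month rats than on the 6 from older rats, at 1.37 to 2.01 and 2.21 to 2.53 for beta-actin, 0.038 to 0.43 and 0.57 to 1.09 for Gapdh and 1.06 to 1.64 and 2.16 to 3.30 for hexokinase. Within a set the hexokinase signal was 1.41 ± 0.14 in hyperplasia (n = 8) and 1.12 ± 0.08 in young wild type (n = 2), with all 8 arrays above both pools (exact permutation p = 0.0444, 0.266 adjusted over 6 tests), and 2.83 ± 0.48 in pheochromocytoma (n = 4) and 2.61 ± 0.44 in old wild type (n = 2), with an exact permutation p of 0.733. The Gapdh signal was 0.22 ± 0.13 and 0.23 ± 0.07 in the young groups and 0.81 ± 0.21 and 0.65 ± 0.02 in the older ones (exact permutation p = 0.956 and 0.4). The beta-actin signal was 1.62 ± 0.21 in hyperplasia (n = 8) and 1.57 ± 0.03 in young wild type (n = 2), and 2.34 ± 0.15 in pheochromocytoma (n = 4) and 2.25 ± 0.02 in old wild type (n = 2), with an exact permutation p of 0.911 and 0.733.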
